A study of Mus musculus with 36 samples.

How the data were processed

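RNA sequencing was done on EGFP-positive neoplastic cells sorted from 36 mouse lung tumours, 9 in each of 4 groups set by the EML4-ALK variant (1 or 3) and the guide (sgNeo or sgSetd2). RNA was isolated with a PicoPure kit, libraries were made with a SMART-Seq mRNA kit and read in pairs on a NovaSeq instrument, per the labels' protocols. The authors deposited 1 table of raw read counts per gene, with a column per tumour and versioned Ensembl gene IDs. Reads were aligned with STAR 2.5.3a, and R 4.2 and DESeq2 1.38.3 are also named, per the submitters' processing notes. The counting tool, its use of strand, the genome build and the annotation are not given in the sources used here. Such a kit does not mark strand, so antisense and overlapping genes are uncertain, and near-identical copies may share reads.

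The table holds 49585 gene IDs, of which 49326 matched GENCODE mouse release 21 (GRCm38) by ID, version digits left aside, and took their symbols and coordinates from it, while 259 had no symbol. Coordinates are those of this annotation and may not be those of the build the authors used. No column was without a sample. Groups came from the labels. The 36 sample titles carry 12 codes, 3 per group and 3 tumours per code. The labels do not say what a code is, so tumours of a code were taken as repeated samples of 1 unit, and p-values measure the spread between codes. The labels give no sequencing batch or date, and none could be tested. No pair of libraries was identical.

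Counts of the 3 tumours of a code were summed, and the 12 units were fitted together with edgeR 4.0.16 in R 4.3.3: filterByExpr by group left 20009 genes, TMM scaled the libraries, and glmQLFit (robust) with glmQLFTest gave log2 fold changes and p-values, adjusted by Benjamini-Hochberg at 0.05. The test gives no SE, so each SE printed is the absolute log2 fold change divided by the square root of the F statistic. The 6 contrasts were sgSetd2 minus sgNeo in Variant 1, in Variant 3 and averaged over both, Variant 3 minus Variant 1 in sgNeo and in sgSetd2, and the interaction. For 40 gene lists, camera of limma 3.58.1 was run two-sided on log2-CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over the lists of a contrast, and again with the correlation estimated and with fry. Setd2 was also tested by exact two-sided permutation. The fit, the contrasts, the lists, the rule for named genes and most alternatives were set before the data were examined.

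Named genes followed a rule: Setd2, Eml4 and Alk, then the 10 genes up and 10 down with the largest log2 fold change among those that passed for Setd2 in each variant and between variants in sgNeo, and 5 and 5 for the other 3 contrasts. These needed a mean of at least 5 CPM in the higher group (over all units for the interaction and the average), no predicted or clone name and, in contrasts of 2 groups, no overlap of units, which chance gives 10% of genes for 3 against 3. Up to 4 members per list were named by smallest p, and where fewer than 5 genes passed, the 5 of smallest p per direction are given as values. Genes outside that rule (Cyp2f2 and Ugt8a in Variant 3, Scgb1a1, Ptprc, Togaram2, those on chromosome 7, and the list members that passed in the averaged contrast) were chosen after their values were seen. Results of some genes that the rule selects are not reported here. A fold against 1 to 3 counts is given as a ratio of normalised counts with its 95% counting interval, and against 0 counts as a lower bound from a floor of 3 counts over the group. Both cover counting error only. List medians with such genes at their bound equalled the medians printed to 2 decimals for every called list.

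Alternatives were RLE and upper-quartile scaling, no filter and a stricter filter, a minimum log2 fold change of 1, DESeq2 1.42.0 on the sums and on the 36 tumours, edgeR on the tumours, limma voom with codes as random blocks, limma on the mean log2-CPM per code, only the groups compared, the macrophage list or the cell cycle list as a covariate, and leaving out each code and each tumour. Sex of the code (Ddx3y above 50 CPM) as a covariate and leaving out the 4 tumours with Col1a1 above 10 CPM were added after seeing the data. Male codes were 0 of 3 in Variant 1 sgNeo, 1 in Variant 1 sgSetd2, 2 in Variant 3 sgNeo and 1 in Variant 3 sgSetd2. Sex is therefore unbalanced between groups. Leaving out tumours of low total removed none. Other splits of the codes were refitted with the same steps, all 9 others within 2 groups, and 60 drawn at random for the interaction and the average.

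Total counts per tumour ran from 17.9 M to 137.2 M, so that 1 count is a small fraction of 1 CPM in each library. On simulated counts for sgSetd2 against sgNeo in Variant 1, with 18873 genes and 200 of them changed, the edgeR fit found 34% of the 2-fold and 74% of the 4-fold changes with 1 false call. DESeq2 on the same sums found 57% and 83% with 67 false calls. Camera found the shifted list and called 0 random lists. Genes were simulated independently of each other, so this does not test camera on lists whose genes vary together. Figures were drawn with matplotlib 3.10.9.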

Results

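Gene expression was measured by RNA sequencing in EGFP-positive neoplastic cells sorted from mouse lung tumours. The tumours were driven by the EML4-ALK fusion, an oncogene that joins the ALK tyrosine kinase to part of EML4. They carried either variant 1 or variant 3, which differ in how much of EML4 the fusion retains. In each variant the tumours received either a control guide (sgNeo) or a guide against Setd2 (sgSetd2), whose product trimethylates lysine 36 of histone H3. The labels give 4 groups of 9 tumours, and the 9 tumours of a group carry 3 title codes with 3 tumours each. Counts were summed per code, so that each group had n = 3 codes. Total counts ran from 17.9 M to 137.2 M per tumour (median 40.7 M) and from 91.5 M to 212.1 M per code. The group medians per tumour were 26.9 M in Variant 1 sgNeo, 38.7 M in Variant 1 sgSetd2, 39.1 M in Variant 3 sgNeo and 54.7 M in Variant 3 sgSetd2. Over all pairs of the 36 tumours, within and between groups, Spearman correlations across genes lay between 0.876 and 0.963. No 2 libraries held identical values. The first principal component held 12.6% of the variance, and the lowest sgSetd2 tumour on it, at 23.4, lay above the highest sgNeo tumour, at 17.2. Values below are TMM-normalised CPM, given as mean ± SD over the 3 codes. Adjusted p-values are from edgeR's quasi-likelihood test on 20009 genes unless another test is named.

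The targeted gene was examined first. Setd2 (ENSMUSG00000044791.16; GRCm38 chromosome 9, 110532597 to 110618633) stood at 67.7 ± 12.8 CPM in Variant 1 sgNeo codes and at 37.4 ± 2.5 CPM in Variant 1 sgSetd2 codes. The log2 fold change was -0.86 (SE 0.22, adjusted p = 0.0825). All 3 Variant 1 sgSetd2 codes (39.0 CPM in CE475, 38.7 in CE479 and 34.5 in CE483) lay below the sgNeo codes (71.0 in CE467, 53.5 in CE468 and 78.5 in CE472). An exact two-sided permutation test over these codes gave p = 0.1, the smallest value that 3 against 3 allows. Over the 9 and 9 tumours, which are not independent of their codes, Setd2 was 36.9 ± 7.9 against 64.7 ± 15.4 CPM (exact two-sided permutation p = 0.000165). In Variant 3, Setd2 was 54.6 ± 10.3 CPM in sgNeo and 45.7 ± 13.2 CPM in sgSetd2 codes, a log2 fold change of -0.26 (SE 0.22, adjusted p = 0.647). The Variant 3 sgSetd2 codes stood at 33.6 CPM in CE450, 43.8 in CE454 and 59.8 in CE456, and the sgNeo codes at 52.9 in CE428, 65.7 in CE429 and 45.2 in CE433. The exact two-sided permutation test gave p = 0.4 over these codes and p = 0.209 over the tumours (44.5 ± 16.2 against 53.2 ± 11.8 CPM). The 3 tumours of CE456 spread from 34.2 through 56.5 to 81.7 CPM of Setd2, the last of these in tumour 10. Averaged over both variants the log2 fold change was -0.56 (SE 0.15, adjusted p = 0.0501), and permuting codes within variants gave an exact two-sided p = 0.025, where 0.005 was the smallest possible. The change in Setd2 did not differ measurably between variants (interaction log2 difference 0.60, adjusted p = 0.834). Gene-level counts do not show the edited allele, and a guide's insertions or deletions need not lower mRNA. The groups are therefore those of the labels, and Setd2 mRNA is a weak check of them, above all for CE456.

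**Figure D1:**
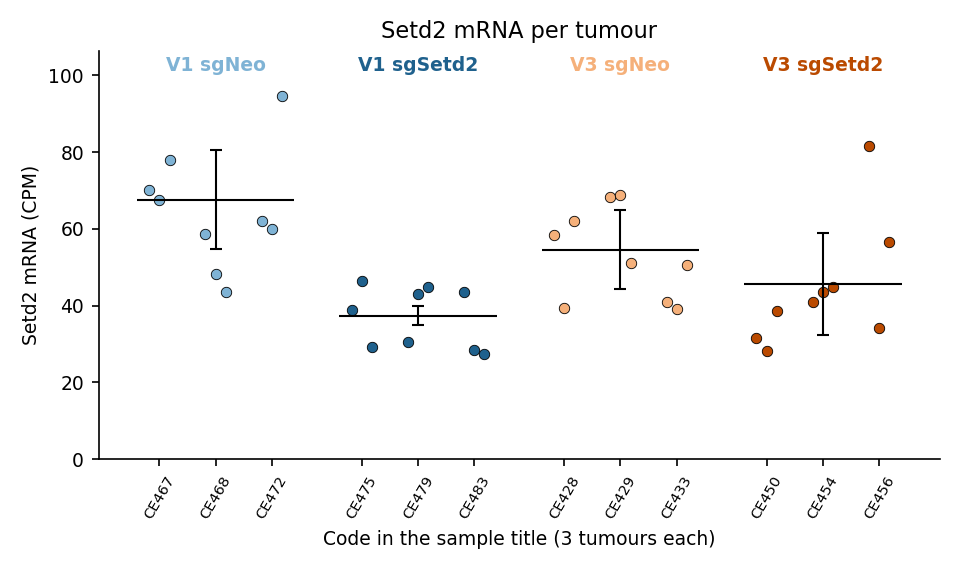
Setd2 in normalised CPM (y axis, linear) in each of the 36 tumours (points), placed by title code and group along the x axis, with lines at the mean and bars at the SD of the 3 codes of a group. The Variant 1 sgSetd2 code means are 37.4 ± 2.5 CPM against 67.7 ± 12.8 CPM in sgNeo, and tumour 10 of CE456 is the highest sgSetd2 tumour at 81.7 CPM.

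The parent genes of the fusion were read next, since mouse Alk and Eml4 counts could include fusion reads, and nothing in gene-level counts separates these. Alk (chromosome 17, 71868972 to 72604627) stood at 25.6 ± 2.9 CPM in Variant 1 sgNeo, 29.7 ± 3.0 in Variant 1 sgSetd2, 16.3 ± 1.1 in Variant 3 sgNeo and 18.6 ± 3.2 in Variant 3 sgSetd2. No Alk contrast passed: Variant 3 minus Variant 1 was -0.65 on the log2 scale in sgNeo (adjusted p = 0.277) and -0.68 in sgSetd2 (adjusted p = 0.146). The sgSetd2 minus sgNeo values of Alk were 0.22 in Variant 1 and 0.19 in Variant 3 (adjusted p = 0.559 and 0.63). Eml4 stood at 44.2 ± 1.3, 55.6 ± 3.4, 34.5 ± 3.8 and 44.5 ± 6.9 CPM in the same 4 groups. Averaged over variants Eml4 rose in sgSetd2 tumours by 0.35 on the log2 scale (SE 0.09, adjusted p = 0.0473), and it did not pass within either variant (0.33, adjusted p = 0.248, and 0.37, adjusted p = 0.221). That call was lost when tumour 6 of CE472 was left out (adjusted p = 0.269).

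The first comparison asked what sgSetd2 did in Variant 1 tumours. Retnla (ENSMUSG00000061100.3; chromosome 16, 48842551 to 48844461), which encodes the secreted resistin-like molecule alpha, rose 35.8-fold, from 144 ± 105 to 5147 ± 2438 CPM (log2 fold change 5.16, SE 0.56, adjusted p = 0.0062). Cyp2f2 (chromosome 7, 27119909 to 27133660), a cytochrome P450 abundant in club cells, rose 12.4-fold, from 19.9 ± 2.5 to 247 ± 46.6 CPM (adjusted p = 0.008). Ugt8a, the enzyme that makes galactosylceramide, went from 1 count in the 9 sgNeo tumours to 5486 counts in the sgSetd2 tumours, a normalised ratio of 6655 (95% counting interval 1194 to 262921, adjusted p = 0.00021). The acute-phase fibrinogen chain genes Fga and Fgg rose from 8.89 to 89.9 CPM and from 15.7 to 97.3 CPM (log2 fold changes 3.34 and 2.63, adjusted p = 0.0115 and 0.0266). The metalloreductase gene Steap4 rose from 11.8 ± 2.8 to 103 ± 43.5 CPM (3.12, SE 0.30, adjusted p = 0.0038). The collagen receptor gene Mrc2 (2.86), the glycosyltransferase gene Gcnt4 (2.43) and the orphan receptor gene Gpr22 (2.26) rose as well. Sall1, a zinc finger transcription factor gene, had 1 count in sgNeo and 1704 counts in sgSetd2 (ratio 2067, 95% counting interval 371 to 81698, adjusted p = 0.0368). Among genes that fell, the collagen gene Col14a1 went from 48 ± 38.2 to 0.165 ± 0.199 CPM (-8.14, SE 1.57, adjusted p = 0.032) and Pgc, the gene of the aspartic protease precursor progastricsin, from 22 ± 16.3 to 0.163 ± 0.142 CPM (-7.05, SE 1.27, adjusted p = 0.0245). Ddc, which encodes aromatic amino acid decarboxylase, fell from 17.2 to 0.473 CPM, and the efflux transporter gene Abcg2 from 36 to 1.57 CPM (adjusted p = 0.0114 and 0.0067). The brush-border gene Vil1 (-4.10), the apelin gene Apln (-3.92), the mucin gene Muc20 (-3.41), Zfp239 (-4.23), Habp2 (-3.51) and Ndrg4 (-3.36) fell too.

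Gene groups fixed in advance were then read in Variant 1, each with the number of its measured members that passed. Of 26 cell cycle genes, 4 fell and none rose over all genes, and 26 fell when adjusted over the list alone. The 4 were the cyclin gene Ccna2 (-2.40, SE 0.39, adjusted p = 0.0195), the checkpoint kinase gene Bub1 (-2.40, adjusted p = 0.0245), Cdk1 (-2.30, adjusted p = 0.0441) and Aurkb (-2.40, adjusted p = 0.047). The list median was -1.57 (camera adjusted p = 1.04e-16), with adjusted p = 0.278 with an estimated correlation. By tumour, 1 sgNeo tumour of each code lay apart in the mean log2(CPM + 1) of this list (5.25 in CE467, 4.86 in CE468 and 5.39 in CE472), while the other 6 ran from 2.31 to 4.07 and the sgSetd2 tumours from 2.54 to 3.53. Summed counts weight tumours by depth, and these 3 tumours held 40.7 M, 67.3 M and 60.9 M counts, so the list median depends on them. With the mean log2-CPM per code, which weights tumours equally, camera still called the list (adjusted p = 3.11e-07). Each sgNeo code holds 1 of these 3 tumours, however, so equal weights do not show whether the fall holds without them. No fit left out all 3. Of 21 DNA damage repair genes, 1 fell over all genes, and 12 fell when adjusted over the list alone (median -0.63, camera adjusted p = 1.49e-07, adjusted p = 0.0931 with an estimated correlation). Of 15 MHC class I presentation genes, 4 rose, and 8 did so adjusted over the list alone: H2-D1 (1.13, adjusted p = 0.0142), B2m (1.55, adjusted p = 0.0245), H2-K1 (1.15, adjusted p = 0.0245) and H2-Q4 (1.54, adjusted p = 0.0491) passed over all genes. Its median was 0.66 (camera adjusted p = 0.000138, adjusted p = 0.536 with an estimated correlation). H2 genes share sequence, so their single values are uncertain. Of 26 interferon response genes, Irf7, a transcription factor of that response, rose (1.80, SE 0.39, adjusted p = 0.0486), and 9 rose adjusted over the list alone (median 1.16, camera adjusted p = 1.39e-07, adjusted p = 0.556 with an estimated correlation). Of 14 club and ciliated cell genes, Cyp2f2 rose, and 6 did so adjusted over the list alone (median 3.05, camera adjusted p = 8.4e-05, adjusted p = 0.556 with an estimated correlation). Scgb1a1, an abundant club cell transcript in this list, had a mean of 36.1 CPM in sgNeo and 120 CPM in sgSetd2 codes and did not pass. The mean log2(CPM + 1) of the club and ciliated list was 5.67, 3.67 and 4.17 in the tumours of CE479. It ran from 2.35 to 2.98 in the other sgSetd2 tumours and from 1.11 to 2.72 in sgNeo, so CE479 adds to the size of this rise. Camera called the list in all 12 fits with a code left out (highest adjusted p = 0.0156). Of 17 AT2 cell genes, the lysozyme gene Lyz2 rose (1.54, SE 0.27, adjusted p = 0.0245), and 2 rose and 1 fell adjusted over the list alone (median 0.46, camera adjusted p = 0.0052, adjusted p = 0.693 with an estimated correlation). The list's mean log2(CPM + 1) was low in 3 sgNeo tumours, tumour 1 of CE467 (9.38), 4 of CE468 (9.75) and 2 of CE472 (10.20). The other sgNeo tumours ran from 11.12 to 11.95 and the sgSetd2 tumours from 10.91 to 11.87, so the rise leans on those 3.

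Of 21 cholesterol synthesis genes in Variant 1, Msmo1 rose (0.71, SE 0.14, adjusted p = 0.0388), and 4 did so adjusted over the list alone (median 0.40, camera adjusted p = 0.000232, adjusted p = 0.681 with an estimated correlation). None of 25 ribosomal protein genes passed over all genes, and 15 fell adjusted over the list alone (median -0.36, camera adjusted p = 1.23e-07, adjusted p = 0.556 with an estimated correlation). Of 5 neutrophil markers none passed over all genes and 2 rose adjusted over the list alone (median 2.34, camera adjusted p = 0.0365, adjusted p = 0.536 with an estimated correlation). That list's call was lost without Retnlg, a near relative of Retnla that could share its reads (camera adjusted p = 0.118). In all, 284 genes changed in Variant 1, 140 higher and 144 lower, of which 107 and 108 changed at least 2-fold, and camera called 9 of 40 lists. No list called in any of the 6 comparisons held with an estimated correlation. The count was 113, 60, 71, 19 and 16 when CE467, CE468, CE472, CE475 and CE483 were left out in turn, from 17 (without tumour 2 of CE472) to 495 (without tumour 4 of CE479) with 1 tumour left out, and 102 with sex as a covariate. With the mean of the cell cycle list as a covariate edgeR called 0 genes, with 888 at an unadjusted p under 0.05. That mean itself differed between the guides in Variant 1, so this covariate also takes out part of any guide effect. Only Ugt8a, Retnla, Cyp2f2 and Steap4, of the 20 genes named by size, passed in all 48 fits that left out 1 code or 1 tumour.

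The same contrast was made in Variant 3 tumours. Retnla rose 166-fold, from 45.5 ± 15.4 to 7578 ± 1246 CPM (7.38, SE 0.62, adjusted p = 0.00035). Steap4 rose from 7.7 ± 1.2 to 147 ± 31.6 CPM (4.26, SE 0.32, adjusted p = 0.0002). Fga and Fgg rose from 6.69 to 147 CPM and from 6.77 to 144 CPM (4.45 and 4.40, adjusted p = 0.0019 and 0.0038). Ugt8a had no count in the Variant 3 sgNeo tumours and 1868 in the sgSetd2 tumours, at least 555-fold higher against a floor of 3 counts over the group (adjusted p = 0.0002). Stk32a, a serine/threonine kinase gene, rose from 7.05 ± 3.78 to 69.7 ± 13.6 CPM (3.30, SE 0.51, adjusted p = 0.0111). Retnlg (4.94, adjusted p = 0.0104), Trp53i11 (6.14, adjusted p = 0.0132), Fam184a (3.90, adjusted p = 0.0487) and the lectin receptor gene Clec12a (3.46, adjusted p = 0.0128) rose from lower levels. Abhd11os rose (4.57, adjusted p = 0.0067), but it is antisense to Abhd11 and use of strand in the counting is not stated, so its reads cannot be told from those of its partner. Pgc (chromosome 17, 47726842 to 47734482) fell from 13.5 ± 10.3 to 0.0108 ± 0.0082 CPM (-10.15, SE 1.53, adjusted p = 0.0103). Apoc1, an apolipoprotein gene, fell from 322 ± 144 to 14.3 ± 12.8 CPM, and Cltrn, which encodes the amino acid transport partner collectrin, from 109 ± 44.5 to 1.18 ± 0.81 CPM (adjusted p = 0.0421 and 0.0409). The neurotrophic factor gene Gdnf fell from 21.9 to 1.03 CPM and the cyclin D2 gene Ccnd2 from 6.28 to 0.218 CPM (adjusted p = 0.0046 and 0.0293). Ctnnd2 (-6.68), Igfbp5 (-4.17) and Tmed6 (-4.78) fell as well. Pcdhb17 (-7.70) and Csf2rb (-6.43) fell too, and both belong to families of near-identical copies, which makes their values uncertain.

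Among the gene groups in Variant 3, 7 of 21 cholesterol synthesis genes rose, and 17 did so adjusted over the list alone. Squalene epoxidase, Sqle, rose from 40.7 ± 1.4 to 123 ± 30.2 CPM (1.60, SE 0.17, adjusted p = 0.0019), and Msmo1 (1.18), Idi1 (1.20) and Lss (1.23) rose with it (adjusted p = 0.0043, 0.0094 and 0.0145). The list median was 0.85 (camera adjusted p = 1.7e-12, adjusted p = 0.468 with an estimated correlation). Of 14 JAK-STAT3 output genes, 3 rose, and 5 rose and 2 fell adjusted over the list alone: the feedback inhibitor gene Socs3 (1.09, SE 0.11, adjusted p = 0.0018), the oncostatin M receptor gene Osmr (1.37, adjusted p = 0.0079) and Fgg passed over all genes (median 0.44, camera adjusted p = 0.0246, adjusted p = 0.468 with an estimated correlation). Of 21 glycolysis and hypoxia genes, Pfkfb3 (1.34, adjusted p = 0.0038) and Ankrd37 (2.15, adjusted p = 0.0251) rose, and 3 did so adjusted over the list alone (median 0.21, camera adjusted p = 0.0085, adjusted p = 0.612 with an estimated correlation). Of 15 MHC class I genes H2-D1 (0.99, adjusted p = 0.0148) and H2-K1 (1.04, adjusted p = 0.0296) rose, and 6 did so adjusted over the list alone (median 0.61, camera adjusted p = 0.0085, adjusted p = 0.612 with an estimated correlation). Of 26 interferon response genes, the RNA sensor gene Oas1a rose (2.61-fold, SE of log2 0.30, adjusted p = 0.0499), and 7 did so adjusted over the list alone (median 0.97, camera adjusted p = 3.68e-06, adjusted p = 0.612 with an estimated correlation).

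None of 25 ribosomal protein genes passed over all genes in Variant 3, and 10 fell adjusted over the list alone (median -0.29, camera adjusted p = 6.05e-08, adjusted p = 0.612 with an estimated correlation). Of 24 p53 targets the kinase gene Plk2 fell (-1.87, SE 0.38, adjusted p = 0.0356), and 1 rose and 4 fell adjusted over the list alone. Camera placed that list lower (adjusted p = 0.0171, adjusted p = 0.748 with an estimated correlation) and its median was -0.26, while its mean was 0.06. Of 5 neutrophil markers Retnlg rose, and 3 did so adjusted over the list alone (median 2.49, camera adjusted p = 0.0171, adjusted p = 0.468 with an estimated correlation). Without Retnlg the camera adjusted p was 0.16. No member of the 17 AT1 cell genes or the 22 nuclear oxidative phosphorylation genes passed over all genes, and 1 and 0 fell adjusted over the list alone (medians -0.20 and -0.17, camera adjusted p = 0.0284 and 0.0316). These became adjusted p = 0.826 and adjusted p = 0.748 with an estimated correlation. Camera called each of these lists in 9 of 12 fits with a code left out (highest adjusted p = 0.52 and 0.335). The AT1 mean log2(CPM + 1) was 6.99, 6.57 and 7.13 in the sgNeo code CE429 and at most 6.35 in any other Variant 3 tumour. In all, 299 genes changed in Variant 3, 176 higher and 123 lower, of which 123 and 106 changed at least 2-fold, and camera called 10 of 40 lists. The count was 81, 78, 101 and 195 when CE428, CE433, CE450 and CE475 were left out in turn, from 176 to 321 with 1 tumour left out, 180 with the cell cycle covariate and 188 with sex. Of the 20 genes named by size, Retnla, Abhd11os, Fga, Fgg, Steap4, Tmed6 and Gdnf passed in all 48 fits that left out 1 code or 1 tumour.

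**Figure D2:**
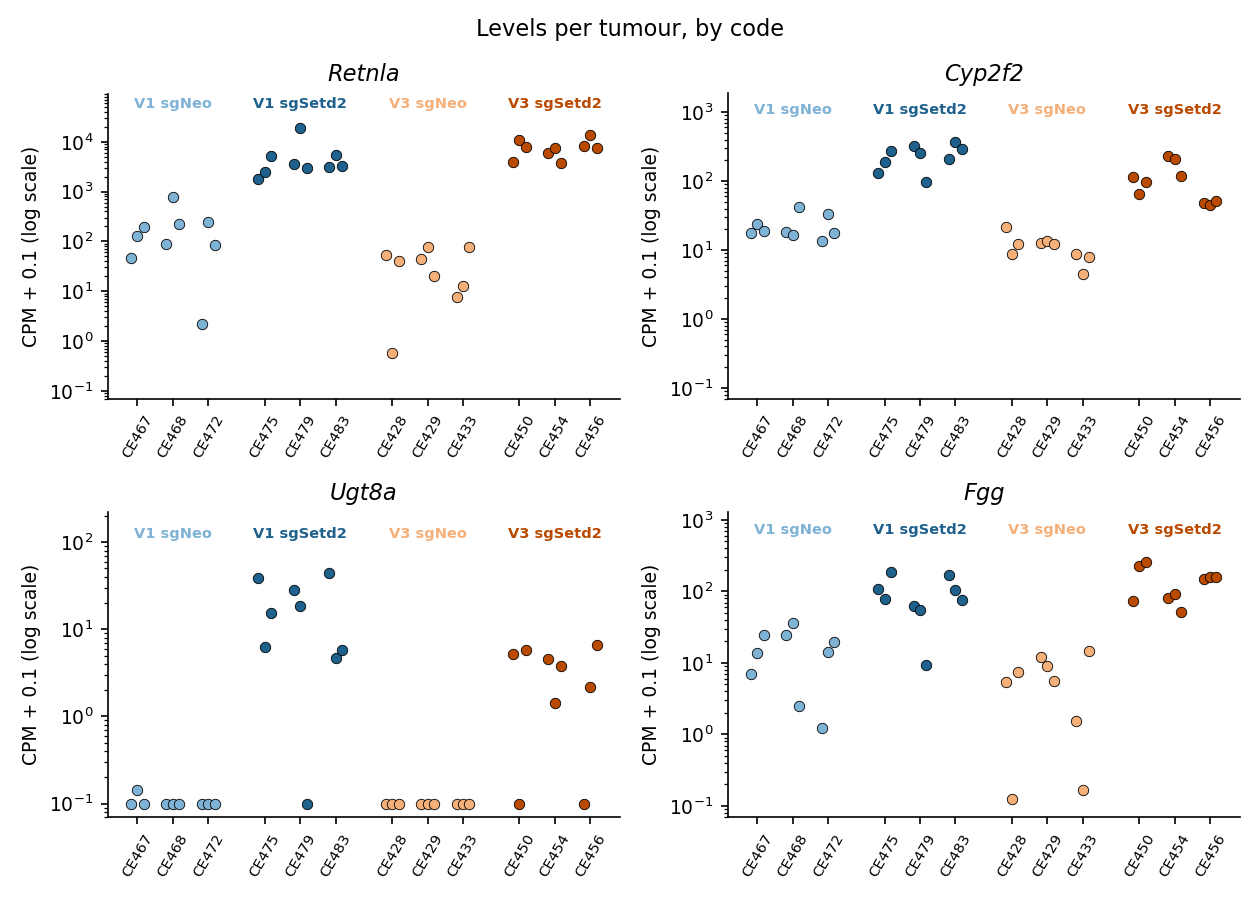
Normalised CPM (y axes, log scale, 0.1 added) of Retnla, Cyp2f2, Ugt8a and Fgg in each of the 36 tumours (points), placed by title code and group along the x axis. All 18 sgSetd2 tumours lie above all 18 sgNeo tumours for Retnla (median 5351 against 64.2 CPM) and Cyp2f2 (162 against 15.0 CPM), while Ugt8a reads 0 in 3 sgSetd2 tumours.

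The Setd2 effects in Variant 1 and Variant 3 come from different libraries but from 1 fit, which shared its filter and estimates of spread. The 2 lists of calls are therefore not independent. Without tumour 3 of CE433, a Variant 3 tumour, Variant 1 gave 67 calls in place of 284. In both variants 101 genes passed in the same direction, 60 higher and 41 lower, and none passed in opposite directions. Independent lists of these sizes would share 1.23 higher and 0.885 lower genes, a reference that may be too low for lists from 1 fit. Retnla, Steap4, Fga, Fgg, Lyz2, Socs3, Osmr, Msmo1, H2-D1 and H2-K1 rose in both, and Pgc fell in both. Lyz2 went from 7439 to 21701 CPM in Variant 1 and from 4682 to 15127 CPM in Variant 3, and Socs3 from 297 to 478 CPM and from 215 to 456 CPM. Cyp2f2 rose in Variant 3 too (3.26, SE 0.44, adjusted p = 0.0068). Of the 284 genes called in Variant 1, 272 had the same sign in Variant 3, and of the 299 called in Variant 3, 286 had the same sign in Variant 1. Across 12784 genes with a mean of at least 1 CPM, the log2 fold changes had a Pearson r of 0.53 and a Spearman rho of 0.51 (0.32 and 0.33 over all 20009 genes), where genes are not independent replicates. The overlap was 35, 38, 41, 52, 28, 30, 11 and 11 genes when CE428, CE433, CE450, CE467, CE468, CE472, CE475 and CE483 were left out in turn, and 37 with sex as a covariate.

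**Figure D3:**
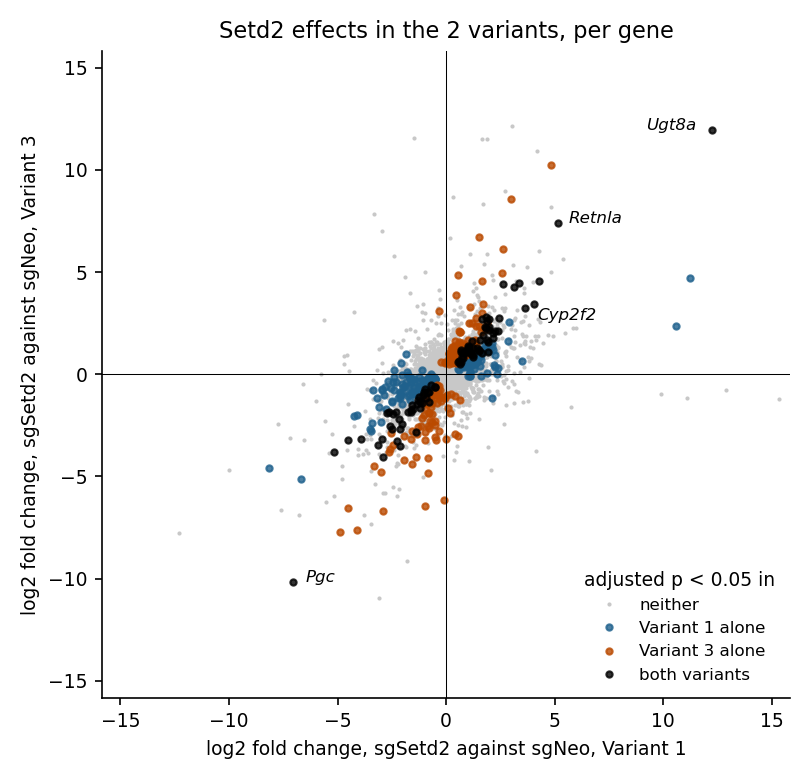
Log2 fold change of sgSetd2 against sgNeo in Variant 1 (x axis) and Variant 3 (y axis) for 12784 genes, 1 point per gene, coloured by the variants in which the gene passed, where points of genes without counts in a group are fitted values and no bounds. The 101 genes that passed in both variants share their direction, and the Pearson correlation is 0.53 over the plotted genes and 0.32 over all 20009 tested.

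Averaged over both variants, the contrast of sgSetd2 with sgNeo gave 1471 genes, 745 higher and 726 lower. Ugt8a had 7354 counts in sgSetd2 and 1 in sgNeo tumours (ratio 7421, 95% counting interval 1332 to 293157, adjusted p = 1.32e-05). Retnla (6.27, SE 0.42, adjusted p = 3.46e-05), Fga (3.90, adjusted p = 0.00026), Retnlg (3.77, adjusted p = 0.0018) and the gluconeogenic gene Fbp1 (3.92, adjusted p = 0.016) rose. Pgc (-8.60, SE 0.99, adjusted p = 0.001), the carbonic anhydrase gene Car4 (-7.13, adjusted p = 0.0216), the gastrokine gene Gkn2 (-7.01, adjusted p = 0.0312), the kinase gene Bmx (-6.81, adjusted p = 0.0078) and Col14a1 (-6.37, adjusted p = 0.0046) fell. Of 26 interferon response genes 9 rose, Irf7 (1.66) and Oas1a (1.28) among them, and 14 did so adjusted over the list alone (median 0.96, camera adjusted p = 5.99e-09, adjusted p = 0.399 with an estimated correlation). Of 21 cholesterol synthesis genes 10 rose, and 17 did so adjusted over the list alone (median 0.71, camera adjusted p = 3.48e-10, adjusted p = 0.399 with an estimated correlation). Of 15 MHC class I genes 7 rose, with B2m 2.59-fold higher (adjusted p = 0.002), and 7 did so adjusted over the list alone (median 0.63, camera adjusted p = 0.00038, adjusted p = 0.399 with an estimated correlation). Of 14 club and ciliated cell genes 4 rose, and 6 adjusted over the list alone: Cyp2f2 (3.45), Dynlrb2 (1.26), Scgb3a2 (3.04) and Tppp3 (1.63) passed over all genes (median 2.09, camera adjusted p = 0.00091, adjusted p = 0.563 with an estimated correlation). Of 14 JAK-STAT3 output genes 5 rose, Socs3 (0.89), Osmr (1.19) and Lrg1 (1.03) among them, and 5 rose and 2 fell adjusted over the list alone (median 0.29, camera adjusted p = 0.0316, adjusted p = 0.394 with an estimated correlation). Of 5 neutrophil markers 2 rose, and 3 adjusted over the list alone (median 2.52, camera adjusted p = 0.0099, adjusted p = 0.394 with an estimated correlation), and without Retnlg camera did not call the list (adjusted p = 0.0826).

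In the same averaged contrast, 5 of 26 cell cycle genes fell, Ccna2 (-1.27, adjusted p = 0.0159) among them, and 20 did so adjusted over the list alone (median -0.90, camera adjusted p = 3.02e-10, adjusted p = 0.394 with an estimated correlation). Camera called this list in Variant 1 but not in Variant 3 alone (adjusted p = 0.087), so the average does not show a fall shared by both. Of 25 ribosomal protein genes 10 fell, and 20 adjusted over the list alone (median -0.34, camera adjusted p = 3.48e-10, adjusted p = 0.399 with an estimated correlation). Of 21 DNA damage repair genes 1 fell over all genes, and 6 adjusted over the list alone (median -0.45, camera adjusted p = 6.19e-05, adjusted p = 0.34 with an estimated correlation). Of 22 nuclear oxidative phosphorylation genes 1 fell, and 3 adjusted over the list alone (median -0.12, camera adjusted p = 0.025, adjusted p = 0.767 with an estimated correlation). Camera called DNA damage repair and club and ciliated cell genes in Variant 1 but not in Variant 3 (adjusted p = 0.243 and 0.106). It called JAK-STAT3 output and oxidative phosphorylation in Variant 3 but not in Variant 1 (adjusted p = 0.0609 and 0.0968). The averaged calls of these lists likewise do not show a change shared by both variants. Of 12 gut and gastric differentiation genes 6 fell, and adjusted over the list alone 6 fell and 1 rose, but camera did not call that list (median -0.30, adjusted p = 0.0594). The 25 genes that write, erase or read H3K36 methylation, Setd2 included, held no gene that passed over all genes or adjusted over the list alone (median -0.04, camera adjusted p = 0.75). Among 23 Polycomb genes 1 rose and 2 fell, with 2 and 4 adjusted over the list alone (median -0.06, camera adjusted p = 0.75). Beside the neutrophil and the club and ciliated cell lists, which were called, 4 lists of other cell types that a sort could carry over were not: medians were -0.82 for 16 macrophage and monocyte genes, 0.66 for 14 fibroblast and smooth muscle genes, 0.64 for 9 endothelial genes and -0.92 for 4 lymphocyte genes, and none of their members passed over all genes. The leukocyte gene Ptprc was at most 3.57 CPM in any sgSetd2 tumour. The averaged count was 845, 902, 970, 900, 728 and 763 when CE428, CE433, CE450, CE468, CE475 and CE483 were left out in turn, and 846 without tumour 2 of CE472. With the mean of the cell cycle list as a covariate 11 genes passed. Of the 10 genes named by size, the calls of Fbp1, Car4 and Gkn2 were lost in at least 1 of the fits that left out 1 code or 1 tumour (highest adjusted p = 0.0544, 0.0736 and 0.0797).

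**Figure D4:**
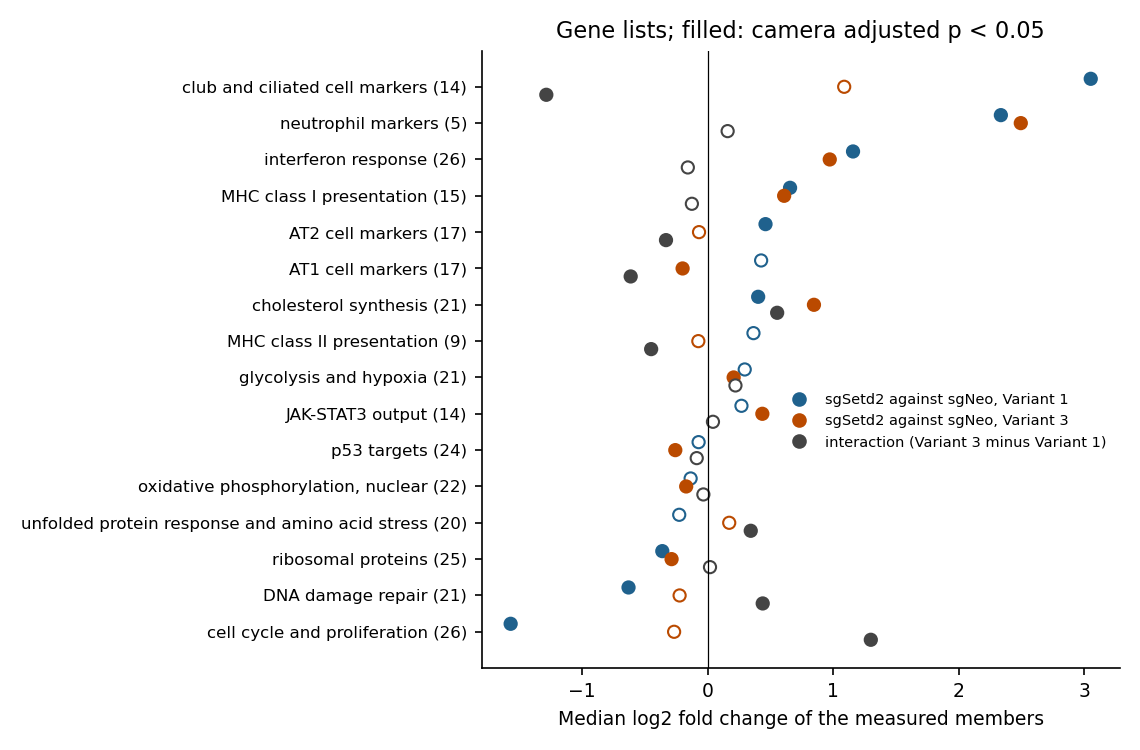
Median log2 fold change (x axis) of the measured members of each gene list (y axis, number measured in brackets) for sgSetd2 against sgNeo in Variant 1, in Variant 3 and for the interaction, with filled points where camera called the list at its preset correlation. The cell cycle list stands at -1.57 in Variant 1 and at 1.30 in the interaction, and no filled point held with an estimated correlation.

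The variants were then compared with each other in sgNeo tumours, which asks how variant 3 differs from variant 1 with Setd2 intact. By the Y-linked gene Ddx3y, 0 of 3 Variant 1 codes and 2 of 3 Variant 3 codes were male here. Sex and variant are therefore partly confounded in this contrast. Asns, the gene of asparagine synthetase (chromosome 6, 7675169 to 7693254), was the single gene that changed. It fell from 51.9 ± 7.9 CPM in Variant 1 to 15.3 ± 0.69 CPM in Variant 3, 3.4-fold lower (log2 -1.76, SE 0.17, adjusted p = 0.0071). The next genes did not pass: the inhibitor heavy chain gene Itih4 stood at -2.10 (adjusted p = 0.0885), Sytl2 at -1.49 (adjusted p = 0.123) and Mphosph9 at -1.40 (adjusted p = 0.138). Vopp1 stood at 1.87 (adjusted p = 0.123), the cilia gene Cfap52 at 1.93 (adjusted p = 0.129), and the calcium-binding genes S100a1 at 0.69 and S100a16 at 0.64, with Mlana at 1.29 (adjusted p = 0.138 each). Of 20 genes of the unfolded protein response and amino acid stress, Asns fell, and 6 fell and 1 rose adjusted over the list alone (median -0.38, camera adjusted p = 0.00048, adjusted p = 0.589 with an estimated correlation). No member of the other lists called here passed over all genes. Camera placed 26 cell cycle genes (median -0.50, adjusted p = 0.00048), 12 WNT output genes (-0.70, adjusted p = 0.0152), 21 DNA damage repair genes (-0.34, adjusted p = 0.0345), 21 glycolysis and hypoxia genes (-0.18, adjusted p = 0.0338) and 21 cholesterol synthesis genes (-0.16, adjusted p = 0.0427) lower in Variant 3. It placed 17 AT1 genes (0.41, adjusted p = 0.0152) and 25 ribosomal protein genes (0.19, adjusted p = 0.0015) higher. Of these 7 lists only AT1 held a member that passed adjusted over the list alone, 1 that rose. With an estimated correlation the WNT list had adjusted p = 0.447 and the other 6 adjusted p = 0.793. With the mean log2-CPM per code camera no longer called the cell cycle (adjusted p = 0.806), DNA damage repair (0.676), AT1 (0.118) or cholesterol synthesis list (0.0676). The AT1 rise leans on 1 code, CE429, whose tumours had a mean log2(CPM + 1) of 6.99, 6.57 and 7.13. The other Variant 3 sgNeo tumours ran from 4.61 to 6.35 and the Variant 1 sgNeo tumours from 4.93 to 6.34. Camera called AT1 in 9 of 12 fits with a code left out (highest adjusted p = 0.578). The Asns call was lost with only these 2 groups in the fit (-1.76, adjusted p = 0.0501), with sex as a covariate (-1.74, adjusted p = 0.122) and without tumour 2 of CE429 (-1.58, adjusted p = 0.103), where the fold stayed near that of the full fit. The adjusted p had a range of 2.11e-17 to 0.122 across settings. No gene passed without CE428, CE429, CE433, CE467 or CE468.

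In sgSetd2 tumours, 26 genes differed between Variant 3 and Variant 1, 1 higher and 25 lower, 24 of the latter at least 2-fold. Other fits gave less one-sided splits, such as 165 higher and 320 lower with DESeq2 on the sums and 200 and 279 with edgeR on the tumours. The dynamin gene Dnm1 rose from 3.97 ± 0.98 to 14.2 ± 1.4 CPM (1.84, SE 0.27, adjusted p = 0.0282). Sytl2 fell from 27.2 ± 7.0 to 2.61 ± 0.19 CPM (-3.39, SE 0.24, adjusted p = 0.0003) and the adenosine receptor gene Adora1 from 20.8 ± 4.2 to 2.3 ± 0.79 CPM (adjusted p = 0.0118). Gdnf (-3.35, adjusted p = 0.0365) and the cytochrome c oxidase subunit gene Cox6a2 (-4.09, adjusted p = 0.0285) fell as well. On chromosome 7 lay 9 of the 26 genes, Sytl2 and Cox6a2 among them, where 2.06 would by chance (exact hypergeometric test, one-sided, adjusted p = 0.0024 over 22 chromosomes). Of 17 AT2 genes the complement gene Hc fell (-1.92, SE 0.26, adjusted p = 0.0205), and 4 fell adjusted over the list alone (median -0.28, camera adjusted p = 0.00043, adjusted p = 0.836 with an estimated correlation). None of 14 club and ciliated cell genes passed over all genes and 5 fell adjusted over the list alone (median -2.34, camera adjusted p = 1.67e-05, adjusted p = 0.729 with an estimated correlation). On this list the Variant 1 tumours of CE479 had a mean log2(CPM + 1) of 5.67, 3.67 and 4.17. The other Variant 1 tumours ran from 2.35 to 2.98 and the Variant 3 tumours from 1.17 to 3.76. Camera called the list in all 12 fits with a code left out (highest adjusted p = 0.0094). No member of the other 9 lists called here passed over all genes. Camera placed the cell cycle list (median 0.93, adjusted p = 1.67e-05), mitochondrial genome transcripts (0.69, adjusted p = 0.00091), ribosomal proteins (0.17, adjusted p = 0.00052), cholesterol synthesis (0.33, adjusted p = 0.0142) and DNA damage repair (0.30, adjusted p = 0.0404) higher. It placed p53 targets (-0.35, adjusted p = 0.00013), MHC class II presentation (-0.42, adjusted p = 0.00091), AT1 genes (-0.43, adjusted p = 0.0142) and immediate early genes (-0.39, adjusted p = 0.0074) lower. Adjusted over the list alone, 2 p53 targets and 1 MHC class II gene fell and no member of the other 7 passed. With an estimated correlation these 9 lists had adjusted p = 0.729 or adjusted p = 0.836. The rise of mitochondrial genome transcripts leans on 1 code, CE456. Their mean log2(CPM + 1) was 7.77, 8.06 and 8.52 in its tumours 6, 9 and 10. The highest other sgSetd2 tumour, tumour 5 of CE454, stood at 7.38. Camera called that list in 11 of 12 fits with a code left out (highest adjusted p = 0.435). Other lists were called in fewer of these fits. AT1, immediate early and cholesterol synthesis genes were called in 9 each (highest adjusted p = 0.16, 0.503 and 0.473). DNA damage repair was called in 8 (highest adjusted p = 0.175), AT2 in 11 and the remaining called lists in all 12. The count of genes was 1, 50, 2, 17 and 7 when CE450, CE454, CE456, CE468 and CE483 were left out in turn, from 3 to 37 with 1 tumour left out, 9 with only these 2 groups in the fit and 1 with the cell cycle covariate. None of the genes named here by size passed in all 48 fits that left out 1 code or 1 tumour.

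The interaction asked whether the effect of sgSetd2 differed between variants. By edgeR 0 genes passed, 1200 had an unadjusted p under 0.05 where 1000 would by chance, DESeq2 on the summed counts called 116, DESeq2 on the 36 tumours 51, edgeR on the tumours 8 and limma with codes as random blocks 2. Among the genes nearest to passing were Cfap52 (-3.36, SE 0.42, adjusted p = 0.0982), Adora1 (-3.23), Slco3a1 (-3.30), Cd83 (-2.54) and Podxl (2.64, SE 0.47), the latter 4 at adjusted p = 0.385. Cfap52 stood at 5.61 and 7.54 CPM in Variant 1 sgNeo and sgSetd2 and at 21.3 and 2.79 CPM in Variant 3. Ndrg4 (2.57), Mapk13 (0.82), Asns (1.21) and Ephb6 (1.45) followed at adjusted p = 0.448. No member of any list passed over all genes. Of 26 cell cycle genes, Bub1 (2.59) and Ccna2 (2.24) passed adjusted over the list alone (list median 1.30, camera adjusted p = 1.38e-11, adjusted p = 0.62 with an estimated correlation). Ccna2 stood at 18.6 and 3.53 CPM in Variant 1 sgNeo and sgSetd2 and at 11.1 and 9.94 CPM in Variant 3. These values come from summed counts, in which deep tumours weigh more. Camera also placed cholesterol synthesis (median 0.55, adjusted p = 0.00013), DNA damage repair (0.44, adjusted p = 0.0002) and amino acid stress (0.34, adjusted p = 0.0314) higher, where 3, 0 and 1 members passed adjusted over the list alone. It placed AT1 (-0.61, adjusted p = 1.69e-05), AT2 (-0.33, adjusted p = 0.0043), club and ciliated cell (-1.29, adjusted p = 0.0305) and MHC class II genes (-0.45, adjusted p = 0.0305) lower, with no member passing adjusted over the list alone. With an estimated correlation DNA damage repair had adjusted p = 0.434, AT2 and club and ciliated cell genes adjusted p = 0.837, and the other 4 adjusted p = 0.76. Of 12 fits with a code left out, camera called MHC class II in 4, amino acid stress in 6, club and ciliated cell genes in 7 and AT2 in 9. The cell cycle, cholesterol synthesis, DNA damage repair and AT1 lists were called in all 12.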

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

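The tests of mislabelling in CE456, of club cell, macrophage and neutrophil RNA, and the comparison of chromosome 7 with the other genes called were chosen only after the result was seen. The tests of mixed cells, copy number and haplotype, and the other splits of the codes, were set before their results were seen.

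Setd2 mRNA in CE456, a Variant 3 sgSetd2 code at 59.8 CPM, lay above the mean of the sgNeo codes of that variant (54.6 CPM) and below 1 of them, CE429 at 65.7 CPM, with 34.2 CPM in its tumour 6. A score over the 284 genes called in Variant 1, a contrast without CE456, argues against mislabelled Setd2-proficient tumours. On it the lowest CE456 tumour lay 0.677 above the highest Variant 3 sgNeo tumour, against an SD of 0.662 in sgNeo. CE456 still entered the shared estimates of spread, so these genes were not chosen wholly apart from it. The score also argues against Setd2-proficient cells as most of tumour 10 of CE456. Tumour 10, with the most Setd2 mRNA (81.7 CPM), scored 116% of the way from the sgNeo mean to that of the other Variant 3 sgSetd2 tumours (SD 51.7%). A smaller share of such cells cannot be told from none. The tumours of CE450 and CE454 themselves ran from 88.6% to 115%, and sgNeo tumours reached 46%. The margin of the first test is small, and Ugt8a, seen in 15 of 18 sgSetd2 tumours, was at 0 in tumour 10 of CE456. It was also at 0 in tumour 3 of CE450, which had 28.2 CPM of Setd2, and in tumour 4 of CE479 in Variant 1. Tumour 4 of CE479 had 9.32 CPM of Fgg, below the 36.3 CPM of the sgNeo tumour 3 of CE468, and was not tested for mixed cells. Edits that leave the mRNA in place may be a candidate explanation, which gene-level counts cannot test.

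Cyp2f2 and Retnla were higher in all 18 sgSetd2 tumours than in any of the 18 sgNeo tumours. RNA from club cells would bring Scgb1a1 at least at the level of Cyp2f2, yet Scgb1a1 lay below Cyp2f2 in 17 of 18 sgSetd2 tumours, the exception being tumour 4 of CE479 (644 against 95.6 CPM). This argues against club cells as the whole source of Cyp2f2. Other values go with some club or ciliated cell RNA, so a share of it stays open: the list was called (median 2.09 averaged over variants), though not with an estimated correlation, Scgb3a2 and Tppp3 lay above all sgNeo tumours in 9 and 7 sgSetd2 tumours, and Scgb1a1 stood at 120 against 36.1 CPM in Variant 1. RNA from macrophages would bring their other abundant transcripts, but Retnla was at least 26.8 times the summed CPM of 16 macrophage and monocyte genes in every sgSetd2 tumour (median 271 times), and the sort for EGFP would remove these cells. The macrophage list was not called (mean log2 fold change -0.87 averaged over variants), and its highest sum was 225 CPM in tumour 3 of CE454. RNA from neutrophils would bring S100a8, but the lowest Retnla of the sgSetd2 tumours (1800 CPM) was 335 times their highest S100a8 (5.37 CPM). This argues against neutrophils as the source of Retnla, while traces of them stay open, as their list was called (median 2.52 averaged over variants) and S100a8 lay above all sgNeo tumours in 5 sgSetd2 tumours. That call was lost without Retnlg (camera adjusted p = 0.0826) and with an estimated correlation. Expression by the neoplastic cells themselves, with Setd2 lost, may be the source as a hypothesis, and RNA from cell types outside these lists stays untested.

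In sgSetd2 tumours 9 of the 26 genes called between variants lay on chromosome 7, against 2.06 by chance, all lower in Variant 3: Clcn4, Gm7696, Zfp419, Slco3a1, Anpep, Gm2115, Sytl2, Galnt18 and Cox6a2, from 7.28 to 128 Mb. A lower copy number of the whole chromosome is argued against by the median log2 fold change of its 981 genes of at least 1 CPM, which was 0.059 (0.064 in sgNeo), while changes of short segments were not tested. A strain haplotype that differs between variants could lower such genes in sgNeo tumours too, as 8 of 9 were, all except Slco3a1. However, 15 of the 17 genes called on other chromosomes were lower there as well (Fisher's exact test, two-sided, p = 1), so the test does not separate the 2 cases. A haplotype and the variant cannot be told apart here, since strain and variant are confounded if they go together, and the variant itself remains an untested explanation.

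Single tumours stood apart from the rest of their group of 9 in 9 of 72 groups of values examined, where about 1 in 20, or 3.6, would by chance. Tumour 2 of CE429 had 137.2 M counts, with the next at 78.2 M. Tumour 3 of CE429 had the lowest Alk of Variant 3 sgNeo, 10.4 CPM. The club and ciliated cell list had a mean log2(CPM + 1) of 3.76 in tumour 3 of CE454. The fibroblast and smooth muscle list stood at 3.57 in tumour 1 of CE467 and at 2.66 in tumour 4 of CE479. The red blood cell list stood at 0.261 in tumour 1 of CE467, 1.57 in tumour 2 of CE479, 1.34 in tumour 1 of CE428 and 0.381 in tumour 10 of CE456.

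The Setd2 effect differed between variants by camera at its preset correlation in 8 lists, none of them with an estimated correlation. The medians of the difference, Variant 3 minus Variant 1, were 1.30 for the cell cycle, 0.55 for cholesterol synthesis, 0.44 for DNA damage repair and 0.34 for the unfolded protein response and amino acid stress. They were -1.29 for club and ciliated cell genes, -0.61 for AT1, -0.45 for MHC class II and -0.33 for AT2 genes. The number called was 5 without CE456 and 5 without CE483, against 8 with all codes.

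Other splits of the codes were refitted. For the averaged Setd2 effect the real grouping gave 1471 genes and the highest of 60 others, drawn at random, 6. Of these 61 splits 1, the real one, gave as many, which argues against chance but does not exclude it. The other splits mix sgSetd2 and sgNeo codes, so any real difference raises their spread and lowers their counts. For the interaction the real grouping gave 0 genes and the highest of the same 60 gave 26, and splits decide nothing there, since any split gives at least 0. Within 2 groups there are 10 splits, too few for a share under 0.05. The real split and the highest other gave 284 and 0 genes for Setd2 in Variant 1, 299 and 0 in Variant 3, 1 and 0 between variants in sgNeo and 26 and 0 in sgSetd2, and in each case 1 of 10 splits gave as many as the real one.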

How the results depend on the processing

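Settings with sex as a covariate or without the 4 tumours of Col1a1 above 10 CPM were chosen only after the result was seen, and the others before. Where a value below moved, the cause was not tested, with 2 exceptions. Fewer genes or samples enter by construction under a stricter filter or when libraries are left out. The cell cycle covariate lowers changes of its own list, and of what goes with it, by construction. RLE (274, 296, 1, 26, 0 and 1478 genes for Setd2 in Variant 1, in Variant 3, variants in sgNeo, variants in sgSetd2, interaction and average) and upper-quartile scaling (302, 337, 1, 31, 0 and 1543) kept every count within 1.5 times.

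In Variant 1, 284 genes became 454 with the stricter filter, 1500 with DESeq2 on sums, 677 with edgeR and 1218 with DESeq2 on the 36 tumours, 136 with the macrophage covariate, 102 with sex and 0 with the cell cycle covariate, where edgeR gave 888 at an unadjusted p under 0.05. In Variant 3, 299 became 1337 with DESeq2, 1361 with edgeR and 1808 with DESeq2 on tumours, 1058 with limma and codes as random blocks, 563 with mean log2-CPM, 172 with only the 2 groups, 180 with the cell cycle and 188 with sex. Between variants in sgNeo, 1 became 4 without a filter, 3 with the stricter one, 393 with DESeq2, 140 with edgeR and 467 with DESeq2 on tumours, 22 with random blocks, 3 with macrophages, 4 with the cell cycle, 14 without the Col1a1 tumours, 0 with only the 2 groups and 0 with sex. In sgSetd2, 26 became 44, 48, 485, 479, 845 and 256 under the same first 6 settings, 68 with mean log2-CPM, 9 with only the 2 groups and 1 with the cell cycle. The interaction gave 1 without a filter, 116, 8, 51 and 2 with the other fits in that order, and 1 with macrophages. The average, 1471, became 665 with a minimum log2 fold change of 1, 2869, 2706, 3158 and 2237 with the same fits, and 11 with the cell cycle. The overlap, 101, became 442 at an unadjusted p under 0.01, 307 with edgeR on tumours and 37 with sex. The share of higher among all calls was 66.8% in Variant 1 and 64.6% averaged with mean log2-CPM, and 71.1% in Variant 1 with random blocks, against 49.3% and 50.6% with summed counts. Between variants in sgSetd2 it was 17.6% with mean log2-CPM, 36.3% with random blocks, and 41.8% with edgeR and 41.9% with DESeq2 on tumours, against 3.85%. In simulated data DESeq2 made 67 false calls on sums and 63 on tumours, and edgeR 1 and 18.

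Called lists, 9, 10, 8, 11, 8 and 10 in the order above, became 0 in all 6 with an estimated correlation, and with fry 4, 3, 0, 0, 0 and 10. Mean log2-CPM gave 4 in sgNeo, and elsewhere lost neutrophil markers in Variant 1, AT1 and JAK-STAT3 in Variant 3, DNA damage repair in sgSetd2 and the interaction, MHC class II in the interaction and JAK-STAT3 averaged. Setd2 in Variant 1 (-0.86) passed with DESeq2 (-0.84, adjusted p = 0.0075), edgeR (-0.81) and DESeq2 on tumours (-0.80, adjusted p = 0.00061), random blocks (-0.82) and exact permutation of tumours (-0.81), and did not with the cell cycle covariate (-1.48, adjusted p = 0.882). Averaged (-0.56) it passed with upper-quartile scaling (-0.55), without a filter (-0.55), with the stricter one (-0.55), DESeq2 (-0.55), edgeR (-0.54) and DESeq2 on tumours (-0.53, adjusted p = 0.00044), random blocks (-0.55), mean log2-CPM (-0.55) and without the Col1a1 tumours (-0.59), and did not with the cell cycle covariate (-0.93, adjusted p = 0.288). In Variant 3 it passed in no setting.

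With 1 code left out, counts ran from 16 to 360 in Variant 1, 78 to 304 in Variant 3, 0 to 1 between variants in sgNeo, 1 to 50 in sgSetd2, 0 to 0 for the interaction and 728 to 1501 averaged, and the overlap from 11 to 130. With 1 tumour left out they ran from 17 to 495, 176 to 321, 0 to 5, 3 to 37, 0 to 1 and 846 to 1681. Codes that moved a count by over 1.5 times were, in Variant 1, CE467 (113), CE468 (60), CE472 (71), CE475 (19) and CE483 (16), and in Variant 3 CE428 (81), CE433 (78), CE450 (101) and CE475 (195). Between variants they were CE428, CE429, CE433, CE467 and CE468 in sgNeo (0 each), and CE450 (1), CE454 (50), CE456 (2), CE468 (17) and CE483 (7) in sgSetd2. For the average they were CE428 (845), CE433 (902), CE450 (970), CE468 (900), CE475 (728) and CE483 (763). For the overlap they were CE428 (35), CE433 (38), CE450 (41), CE467 (52), CE468 (28), CE472 (30), CE475 (11) and CE483 (11). Single tumours did so in Variant 1: tumour 1 of CE428 (175), CE467 (76), CE468 (51) and CE479 (148), 2 of CE472 (17), 3 of CE433 (67), 4 of CE479 (495) and 6 of CE472 (445). In Variant 3 they were tumour 1 of CE468 (194) and 2 of CE428 (176) and CE472 (191), and averaged 2 of CE472 (846). In sgNeo they were tumour 1 of CE429 (3), CE467 (3) and CE475 (2), 2 of CE429 (0) and CE467 (2), 3 of CE429 (5), CE467 (2) and CE475 (2), 4 of CE468 (2) and 6 of CE472 (3). In sgSetd2 they were tumour 1 of CE468 (17), 2 of CE429 (7), 3 of CE433 (3) and CE467 (11) and 9 of CE456 (16). The interaction gave 1 without tumour 1 of CE479, 3 of CE475, 5 of CE454 or 6 of CE472. Called lists ran from 9 to 11, 8 to 13, 6 to 11, 7 to 14, 5 to 12 and 9 to 13 in the order above, with 7 in sgSetd2 without CE450, and 5 for the interaction without CE456 or CE483. Setd2 ran from -1.003 to -0.74 in Variant 1 (tumours -0.94 to -0.74), -0.49 to -0.073 in Variant 3 (-0.35 to -0.19) and -0.68 to -0.47 averaged (-0.60 to -0.50). It passed in Variant 1 without CE456 (adjusted p = 0.047), and averaged without CE456 (adjusted p = 0.019), without CE468 (0.0465) and in 14 of 36 fits without a tumour.

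Of 309 results for named genes 114 passed. Of these, 114 kept the call under RLE, upper-quartile scaling and the stricter filter, 112 under DESeq2 on sums and on tumours, 104 under edgeR on tumours, 91 with macrophages, 91 without the Col1a1 tumours, 90 without a filter, 88 with mean log2-CPM, 86 with sex, 71 with random blocks, 103 with a minimum log2 fold change of 1 and 26 with the cell cycle, 47 of 72 with only the 2 groups compared, and 39 in every fit with 1 code or tumour left out. With the cell cycle covariate the sign turned for Cdk1 in Variant 1 (0.090) and averaged (0.094), Aurkb (0.026) and Mmp8 (-3.64) in Variant 1, Col4a4 in sgNeo (-0.0095), and Gprc5a (0.11), Sdf2l1 (-0.15) and Eml4 (-0.091) in the interaction. Cdk1 and Aurkb are members of that list, so adjusting for its mean takes out most of their change by construction. The interaction of Eml4 also turned with edgeR (-0.033) and DESeq2 (-0.050) on tumours, random blocks (-0.081), mean log2-CPM (-0.076) and macrophages (-0.024). That of Alk turned with macrophages (0.037) and sex (0.058). Left-out libraries turned the interaction of Eml4 (-0.19 without tumour 2 of CE472, up to 0.26) and Alk (0.15 without tumour 6 of CE472, down to -0.19), Mmp8 in Variant 1 (-0.56 without tumour 1 of CE483, up to 2.05) and S100a8 in Variant 3 (-0.99 without CE450, up to 3.16). In sgSetd2 Hsph1 (0.13, down to -3.51), Hspa1b (0.047, down to -2.24) and Dnajb1 (0.069, down to -1.16) turned without CE479, and in sgNeo Mcm4 with mean log2-CPM (0.036). Of these genes only Cdk1 and Aurkb had passed. Total counts per code, at least 91.5 M, limit genes near 0 CPM.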

Other observations

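The test of a link between the cell cycle and AT2 lists, and the genes named here, were chosen only after the result was seen, whereas the lists were not.

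Several lists that camera did not call held single genes that passed in sgSetd2 against sgNeo tumours, averaged over variants, given here as gene, log2 fold change and edgeR adjusted p. Of 24 lung tumour suppressor genes 1 fell, Trp53, the gene of p53 (-0.84, adjusted p = 0.0017), and 4 fell adjusted over the list alone (median -0.01, camera adjusted p = 0.226). Of 19 MAPK output genes the ETS factor gene Etv4 (-0.66, adjusted p = 0.0087) and the phosphatase gene Dusp4 (-0.91, adjusted p = 0.0099) fell, and 4 did so adjusted over the list alone (median -0.06, camera adjusted p = 0.0594). Of 20 NRF2 targets the heme oxygenase gene Hmox1 (0.77, adjusted p = 0.0033) and the glutathione synthesis gene Gclc (0.73, adjusted p = 0.007) rose, whereas Pir (-1.92, adjusted p = 0.0065), Gclm (-0.51, adjusted p = 0.024) and Gstm1 (-1.39, adjusted p = 0.0312) fell, and 5 rose and 5 fell adjusted over the list alone (median -0.20, camera adjusted p = 0.372). Of 11 high-grade lung tumour markers Cd44 rose (0.60, adjusted p = 0.0054) and the transcription factor gene Sox9 fell (-3.23, adjusted p = 0.0276). Of 12 WNT output genes the receptor genes Lgr4 (1.88, adjusted p = 0.0121) and Lgr5 (3.50, adjusted p = 0.0258) rose. Of 19 transitional alveolar genes Lgals3 rose (1.16, adjusted p = 0.0233) and Clu fell (-1.15, adjusted p = 0.0208).

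In the gut and gastric list, the 6 genes that fell were Vil1 (-3.05, adjusted p = 0.0074), the cathepsin gene Ctse (-2.99, adjusted p = 0.0102), Gkn2 (-7.01) and the transcription factor genes Foxa3 (-1.25, adjusted p = 0.0244), Gata6 (-0.37, adjusted p = 0.0465) and Hnf4a (-4.11, adjusted p = 0.0496). Of 23 Polycomb genes Cbx7 rose (0.75, adjusted p = 0.0088), and Bmi1 (-0.66, adjusted p = 0.0251) and Jarid2 (-0.46, adjusted p = 0.0465) fell. Of 22 splicing factor genes Hnrnpa1 (-0.42, adjusted p = 0.0152) and Snrpb (-0.39, adjusted p = 0.0387) fell. Togaram2, a gene of ciliary microtubule regulation, was higher in all 18 sgSetd2 tumours than in any sgNeo tumour, with medians of 96.9 and 17.6 CPM.

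Among the 18 sgNeo tumours of both variants, those with a high mean of the cell cycle list had a low mean of the AT2 list. The Pearson r was -0.83 (permutation p = 0.0025 within codes, two-sided, adjusted p = 0.005 over 2 relations) and the Spearman rho -0.87 (permutation p = 0.00025, adjusted p = 0.0005). Without the 2 tumours farthest from the cell cycle median r was -0.78. In the 18 sgSetd2 tumours r was -0.38 (permutation p = 0.329) and rho -0.54 (permutation p = 0.0734), with r = -0.48 without the 2 farthest. Whether the relation differs between guides was not tested. The relation was seen in these tumours before it was tested, so whether tumours that lost alveolar identity proliferate more stays an untested hypothesis.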
